A study of Mus musculus with 6 samples.

How the data were processed

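Gene expression was measured on 6 single-colour Affymetrix arrays, 1 per RNA sample of mouse bone marrow-derived macrophages. Per the labels, 3 samples were untreated controls and 3 had received JG-98, an inhibitor of Hsp70 chaperones, at 0.3 micromole for 16 hours. The labels give the dose as an amount and name no volume, and they name no vehicle for the controls. Total RNA was labelled with biotin by a whole-transcript kit, per the labels' protocols.

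The authors deposited log2 expression values, 1 per probe set and array. RMA, the affy package and R 2.15.1 are named in the submitters' processing notes, without their roles. RMA, as the method is generally defined, corrects background, normalizes arrays against each other by quantiles and summarises probes into a log2 value. It compresses differences between dim probe sets, and a shift of all genes together would be removed by its normalization. The 6 deposited columns did not have identical distributions, with medians between 4.08 and 4.24. A genome build is not given in the sources used here, so no coordinates are printed. No detection p-value was used here, and low values cannot be told from background. The number of arrays limits the precision of every value.

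Each of the 25206 probe sets carries an Entrez gene number. The platform annotation gave 1 symbol for 23185 of them, several for 0 and none for 2021, and no symbol stood on more than 1 probe set. Symbols were updated through the Entrez number in a RefSeq gene table of assembly GRCm38.p6, in which all 23185 matched, and which was used for names only. Probe sets without a symbol were tested but are not named.

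Samples were grouped by their labels, and no covariate was used. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the deposited log2 values. Benjamini-Hochberg adjustment ran over all 25206 probe sets, with a threshold of 0.05. A log2 difference is JG-98 minus control, and its SE is the moderated one. Beside the residual degrees of freedom of 4, the moderated variances drew on 2.59 prior degrees of freedom. No label says that the replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

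Gene lists for stress responses, macrophage functions, cell processes and other cell types were fixed before the data were examined. So were the tests, the rule for naming genes and the other settings to be tried. Of 39 lists, 38 had at least 3 measured members. The list of mitochondrially encoded transcripts had too few and was not tested. Lists were tested with limma's camera (two-sided) at its preset inter-gene correlation of 0.01, over the 23185 named genes, with Benjamini-Hochberg adjustment over the 38 lists. Camera with a correlation estimated per list, and fry, were run beside it. Members of a list that passed are counted over all genes tested and also adjusted over the list alone. The same gene can stand in several lists.

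Genes are named by 3 rules. The first takes genes with an adjusted p under 0.05 whose JG-98 values all lay on one side of all control values, up to 15 per direction. The second takes the 4 members of a described list with the smallest adjusted p. The last always includes Hspa1a, Hspa1b, Hspa8, Hspa9, Hspa5, Bag3 and Csf1r. Any other gene is said to have been chosen after its values were seen.

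Simulated data took the real mean levels, with each variance drawn from the prior fitted to the data, whatever the level. The fit was tested on them in 20 simulations of 25206 probe sets with 200 changed. For JG-98 against control it recovered 18.4% of probe sets changed by 0.5 on the log2 scale, 79.0% of those changed by 1 and 95.5% of those changed by 2. Of its calls, 4.11% were false. A list of 32 members shifted by 0.25 was called in 20 of 20 simulations, and 0% of the unshifted lists were called. The simulated genes varied independently, so this does not test the preset correlation. Their variance did not depend on level, so the rates hold under the assumptions of the fit and may differ for dim and bright probe sets. In the real data, splits of the arrays other than by treatment called 1 to 13 lists.

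The other settings were median centring of each array, a further quantile normalization, 2 filters on dim probe sets, an intensity trend and a robust prior in eBayes, and array weights. Further settings were the replicate number as a block, leaving out each array in turn, camera with an estimated correlation, and fry. Averaging several probe sets of a gene could not be applied, because each gene had 1. Array weights used statmod 1.5.0.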

Results

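The 6 arrays measured the transcripts of bone marrow-derived macrophages, which are macrophages grown from mouse marrow, in 3 untreated samples and 3 samples given the Hsp70 inhibitor JG-98 for 16 hours. Hsp70 proteins are chaperones that bind unfolded protein, and the comparison asks how blocking them alters macrophage gene expression. Array medians lay between 4.08 and 4.24 on the log2 scale. Across probe sets, JG-98 replicate 3 correlated with the other arrays at 0.992 to 0.993, and the other 5 arrays with each other at 0.995 to 0.996. The first principal component, with 36.7% of the variance, set that array apart from the other 5, and the second, with 20.8%, parted the JG-98 from the control arrays.

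With JG-98, 8 genes rose and 2 fell at an adjusted p under 0.05 in limma, and in all 10 the 3 JG-98 values lay on one side of the 3 control values. Trib3, a pseudokinase induced by ATF4 and CHOP, rose by a log2 difference of 1.58 ± 0.079 (SE, n = 3 per group), which is 2.98-fold (limma adjusted p = 0.0094). Also higher were Asns, which makes asparagine, at 0.92 ± 0.077, Mthfd2, an enzyme of mitochondrial one-carbon metabolism, at 0.89 ± 0.068, and Nupr1, a stress-induced chromatin protein, at 0.77 ± 0.064. The glycine transporter gene Slc6a9 rose by 1.17 ± 0.098. Cox6a2, the muscle-type subunit of cytochrome c oxidase, rose by 1.39 ± 0.089. Tarm1, an activating receptor of myeloid cells, rose by 1.18 ± 0.083, and Ptgir, the prostacyclin receptor, by 0.92 ± 0.074. Ms4a4a, a membrane protein of macrophages with many close relatives whose transcripts can share probes, fell by 1.59 ± 0.097, which is 3.01-fold lower (limma adjusted p = 0.0152). Mmp27, a matrix metalloproteinase, fell by 0.85 ± 0.069.

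Of these 10 genes, 5 changed by 2-fold or more, 4 of them upward. At an unadjusted p under 0.05 there were 2097 probe sets, 967 higher and 1130 lower, where chance gives 1260. Another split of the arrays, control replicate 1, JG-98 replicate 1 and JG-98 replicate 2 against the others, gave 2636. The remaining splits into equal groups gave 755 to 1416, so an excess over 1260 is not specific to the treatment. All JG-98 values lay on one side of all control values in 15.6% of probe sets, where chance gives 10%. Without JG-98 replicate 3, limma called 5 genes, of which 4 were among these 10 and the other was Slc7a11. Without any single one of the other 5 arrays it called 0, with 1576 to 2046 probe sets at an unadjusted p under 0.05. The 10 genes kept their direction each time. The count and its balance depended on the fit, with 90 genes (49 higher, 41 lower) under a stricter filter for dim probe sets, 254 (127 higher, 127 lower) with an intensity trend and 25 (17 higher, 8 lower) with array weights. After median centring of the arrays there were 7 (5 higher, 2 lower), and the calls of Asns, Nupr1 and Ptgir were lost at differences of 0.90, 0.75 and 0.90 (adjusted p = 0.064, 0.082 and 0.055). With the replicate number as a block, limma called 0 genes (smallest adjusted p = 0.22), though no label says what that number stands for.

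**Figure D1:**
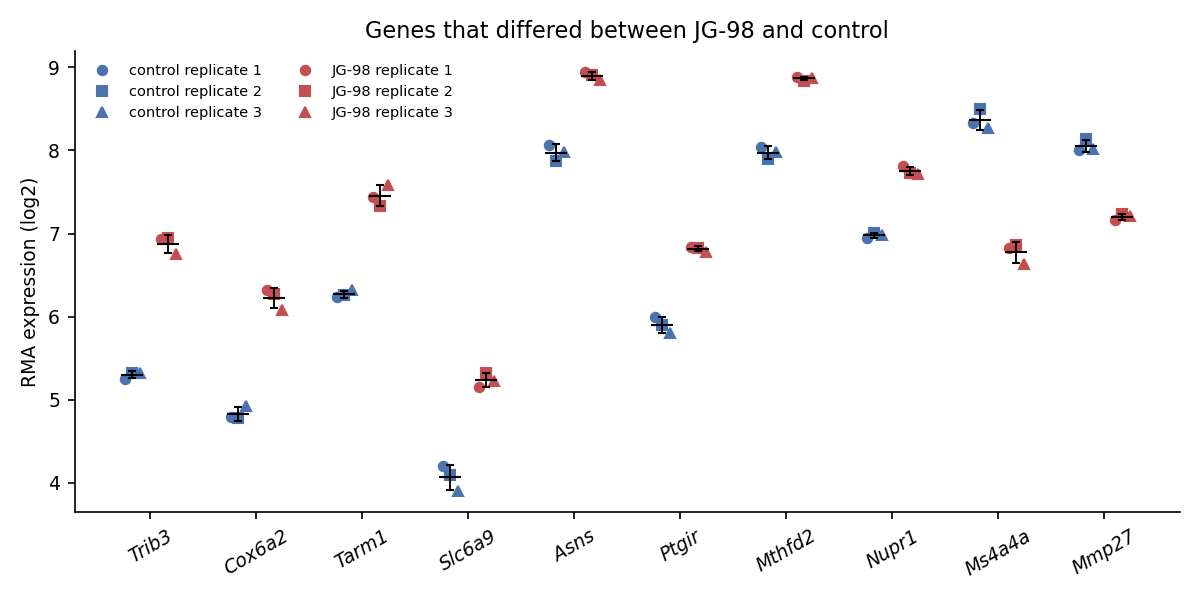
RMA log2 expression (vertical axis) of the 10 genes that passed limma at an adjusted p under 0.05, with a point for each control (blue) and JG-98 (red) array, the group mean as a black bar and its SD as the error bar. For each gene the 3 JG-98 points lie apart from the 3 control points, from 1.58 higher for Trib3 to -1.59 for Ms4a4a on the log2 scale.

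Transcripts of genes listed for the integrated stress response, the program of the transcription factors ATF4 and CHOP, were higher with JG-98. Of 32 measured members, 4 rose over all genes tested (Trib3, Mthfd2, Nupr1 and Asns) and 20 rose when adjusted over the list alone. Over all genes the count was 2 without JG-98 replicate 3, namely Trib3 and Slc7a11, so of those 4 only Trib3 held. It was 0 without any other array, and over the list alone the count was 16 to 21. The median member was 0.25 higher on the log2 scale, and 24 members had all JG-98 values above all control values. Camera gave an adjusted p of 3.57e-25, and this list alone stayed past the threshold with an estimated correlation (adjusted p = 0.011 with an estimated correlation). The mean of its members rose by 0.36 more than that of the heat shock list and by 0.32 more than that of the endoplasmic reticulum list, genes shared between lists left out. An exact two-sided permutation test gave p = 0.1 for either difference, the smallest that 3 against 3 samples allow.

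Neither the cytosolic Hsp70 genes nor the heat shock response list passed the test. Hspa8, the constitutive Hsp70, differed by 0.01 ± 0.076 on the log2 scale (SE, n = 3 per group), and by -0.01 after median centring, which moves all genes alike. The inducible Hspa1a and Hspa1b differed by 0.31 ± 0.32 and 0.13 ± 0.33, at mean levels of 3.2 to 3.8 where background is not excluded. The co-chaperone Bag3 differed by -0.06 ± 0.074. None of the 26 measured heat shock (HSF1) targets passed, over all genes or adjusted over the list alone. Their median was 0.06 higher (camera adjusted p = 0.085, and adjusted p = 0.61 with an estimated correlation). Without JG-98 replicate 3 that list passed (median 0.10, camera adjusted p = 0.0050), without JG-98 replicate 2 its median was 0.028, and it passed in 5 of 15 settings in all (adjusted p from 0.0050 to 0.61). In the list of 33 Hsp70 family members and co-chaperones, the mitochondrial Hsp70 Hspa9, at 0.42 ± 0.063, and the endoplasmic reticulum chaperone Hyou1, at 0.38 ± 0.068, rose when adjusted over the list alone. Neither rose over all genes (limma adjusted p = 0.19 and 0.25), and both calls were lost without control replicate 2, control replicate 3, JG-98 replicate 1 or JG-98 replicate 2, when the count was 0. As a whole that list did not pass with all arrays (median 0.04, camera adjusted p = 0.074). It passed without JG-98 replicate 3 (median 0.05, camera adjusted p = 0.017) and in 4 of 15 settings in all, and its median was 0.013 without control replicate 2.

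Genes of the endoplasmic reticulum unfolded protein response were shifted upward by a small amount. Hyou1 was the 1 of 27 members that rose when adjusted over the list alone, and 0 did so without any one array. The median was 0.10 higher (camera adjusted p = 1.53e-05, but adjusted p = 0.24 with an estimated correlation). Hspa5, the main chaperone of this compartment, differed by 0.15 ± 0.065 (limma adjusted p = 0.62), and the disulfide isomerase gene Pdia6 by 0.19 ± 0.063. Of 19 mitochondrial chaperones and proteases, 3 rose when adjusted over the list alone, namely Hspa9 and the import components Tomm70a and Timm17a. That count was 1 without any one array other than JG-98 replicate 3. The median of the list was 0.12 higher, and 0.18 higher without control replicate 1 (camera adjusted p = 2.06e-05 with all arrays, and adjusted p = 0.23 with an estimated correlation).

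Oxidative stress genes driven by NRF2 were also higher. Of 22 members, 9 rose when adjusted over the list alone, and 0 over all genes. Slc7a11, which imports cystine and also belongs to the integrated stress response list, was at 1.53 ± 0.19, and the glutathione synthesis gene Gclm at 0.30 ± 0.071. Srxn1, which repairs oxidised peroxiredoxins, was at 0.32 ± 0.065. The count was 5 without control replicate 1, and 1 without control replicate 2, control replicate 3, JG-98 replicate 1 or JG-98 replicate 2. Without JG-98 replicate 3 it was 7, and 1 member, Slc7a11, rose over all genes. The median was 0.16 higher, 0.10 higher without JG-98 replicate 1 and 0.20 higher without JG-98 replicate 3. Camera gave an adjusted p of 6.30e-08 with all arrays, but an adjusted p of 0.30 with an estimated correlation. Against the control mean, the median member was 0.18 and 0.21 higher on JG-98 replicates 1 and 2. On JG-98 replicate 3 it was only 0.042 higher, close to the 0.037 of control replicate 1.

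Ribosome biogenesis genes were higher in 29 of 30 members, 8 of which rose when adjusted over the list alone. The nucleolar genes Gnl3 and Nop2 were at 0.45 ± 0.092 and 0.27 ± 0.068, and Polr1a, the large subunit of RNA polymerase I, at 0.28 ± 0.071. The count was 1 without JG-98 replicate 3 and 0 without any other array. The median was 0.17 higher (camera adjusted p = 1.64e-11, but adjusted p = 0.24 with an estimated correlation). Of 29 glycolysis and hypoxia genes, 3 rose when adjusted over the list alone. These were the oxidoreductase gene Ero1a at 0.52 ± 0.059, the angiogenic factor gene Vegfa at 0.60 ± 0.071 and the phosphofructokinase gene Pfkp at 0.32 ± 0.062. The count was 5 without JG-98 replicate 3 and 2 without JG-98 replicate 2 or any one control. Its median was 0.12 higher (camera adjusted p = 4.28e-07, and adjusted p = 0.14 with an estimated correlation).

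Genes of mitosis and the G2/M phase were lower in all 31 measured members. Of these, 15 fell when adjusted over the list alone and 0 over all genes, and 30 had all JG-98 values below all control values. Cdc20, an activator of the anaphase-promoting complex, and Cenpa, the centromeric histone, were at -0.39 ± 0.073 and -0.38 ± 0.068, and the spindle checkpoint kinase gene Bub1b at -0.29 ± 0.062. The count was 2 without JG-98 replicate 3 and 0 without any other array. The median was -0.21 (camera adjusted p = 1.54e-20, but adjusted p = 0.23 with an estimated correlation). Fry called the list (fry adjusted p = 0.020). The 31 measured genes of DNA replication and the G1/S phase had a median of 0.03 and none passed (camera adjusted p = 0.61). The mean of the mitosis list fell by 0.24 more than that of the G1/S list (exact two-sided permutation p = 0.1, the smallest the design allows).

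**Figure D2:**
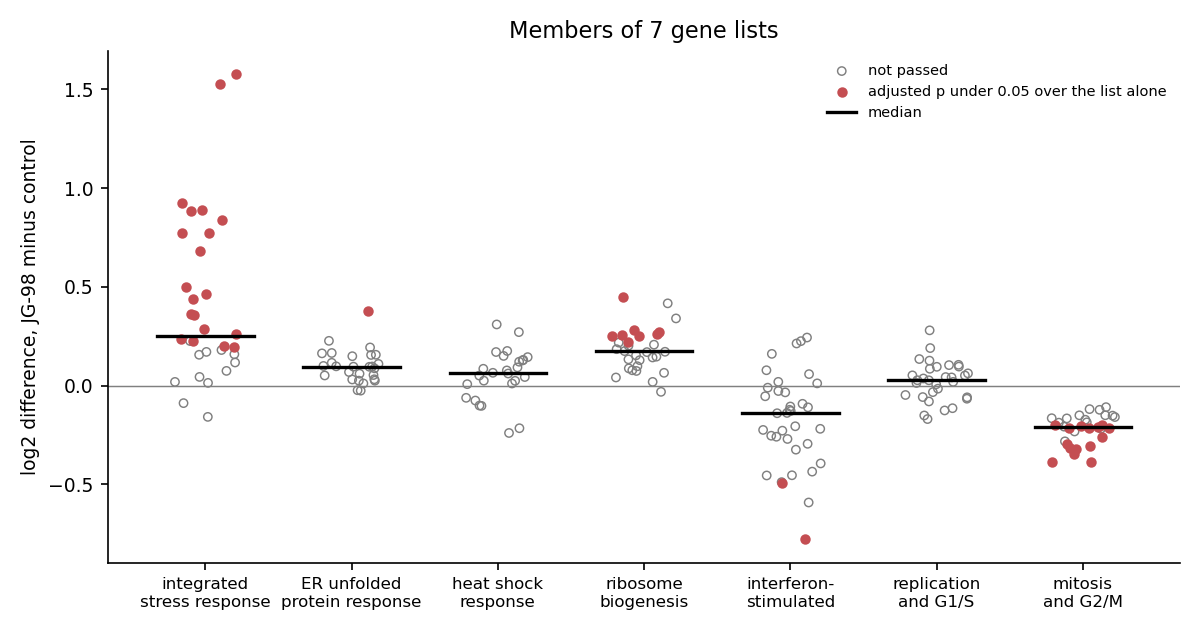
Log2 difference between JG-98 and control (vertical axis) for each measured member of 7 gene lists, with members that passed adjusted over the list alone filled in red and the list median as a black bar. The integrated stress response reaches 1.58 with a median of 0.25, while all 31 mitosis genes lie below 0.

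Inflammatory cytokine and NF-kB target genes were shifted upward, with 8 of 36 members that rose and 1 that fell when adjusted over the list alone. The monocyte chemokine genes Ccl2 and Ccl7 were at 0.59 ± 0.072 and 0.61 ± 0.096, the itaconate-producing Acod1 at 0.71 ± 0.088, and Nfkbie, an NF-kB inhibitor, at -0.31 ± 0.075. Acod1 lay at mean levels of 3.3 to 4.0, where background is not excluded. The number that rose was 4 without JG-98 replicate 3 and 3 without any other array, and the number that fell was 0 without any one of the 6 arrays. The median was 0.05 higher (camera adjusted p = 0.0025, but adjusted p = 0.23 with an estimated correlation). It ranged from 0.027 without control replicate 1 to 0.098 without JG-98 replicate 2. Interferon-stimulated genes were shifted downward, with a median of -0.14 over 36 members, and -0.21 without control replicate 3 (camera adjusted p = 1.53e-05 with all arrays, but adjusted p = 0.23 with an estimated correlation). The interferon-inducible GTPase genes Ifi47 and Gbp3 fell when adjusted over the list alone, at -0.49 ± 0.081 and -0.78 ± 0.14. Gbp3 lay at mean levels of 2.7 to 3.5, where background is not excluded. The number that fell was 10 without JG-98 replicate 3, and 0 without control replicate 1, control replicate 2 or JG-98 replicate 2.

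Genes of macrophage identity had a median of -0.07 over 24 members, none of which passed. Camera called the list (adjusted p = 0.017, but adjusted p = 0.69 with an estimated correlation), and the call was lost without JG-98 replicate 3 (median -0.04, adjusted p = 0.46). The call was also lost without control replicate 1 or control replicate 2, after median centring and with array weights. In fry it was lost too (fry adjusted p = 0.23), and it held in 8 of 15 settings. The complement gene C1qa was at -0.24 ± 0.066 and the growth factor receptor gene Csf1r at -0.09 ± 0.061. Cholesterol biosynthesis genes had a median of -0.10 over 19 members, and none passed (camera adjusted p = 4.0e-04, but adjusted p = 0.30 with an estimated correlation). Insig1, which retains the regulator of this pathway in the endoplasmic reticulum, was at -0.30 ± 0.075. Of 16 cholesterol efflux genes, Apoc2 at -0.48 ± 0.072 and the exporter gene Abca1 at -0.42 ± 0.074 fell when adjusted over the list alone. The list did not pass camera (camera adjusted p = 0.075) but passed fry (fry adjusted p = 0.020).

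**Figure D3:**
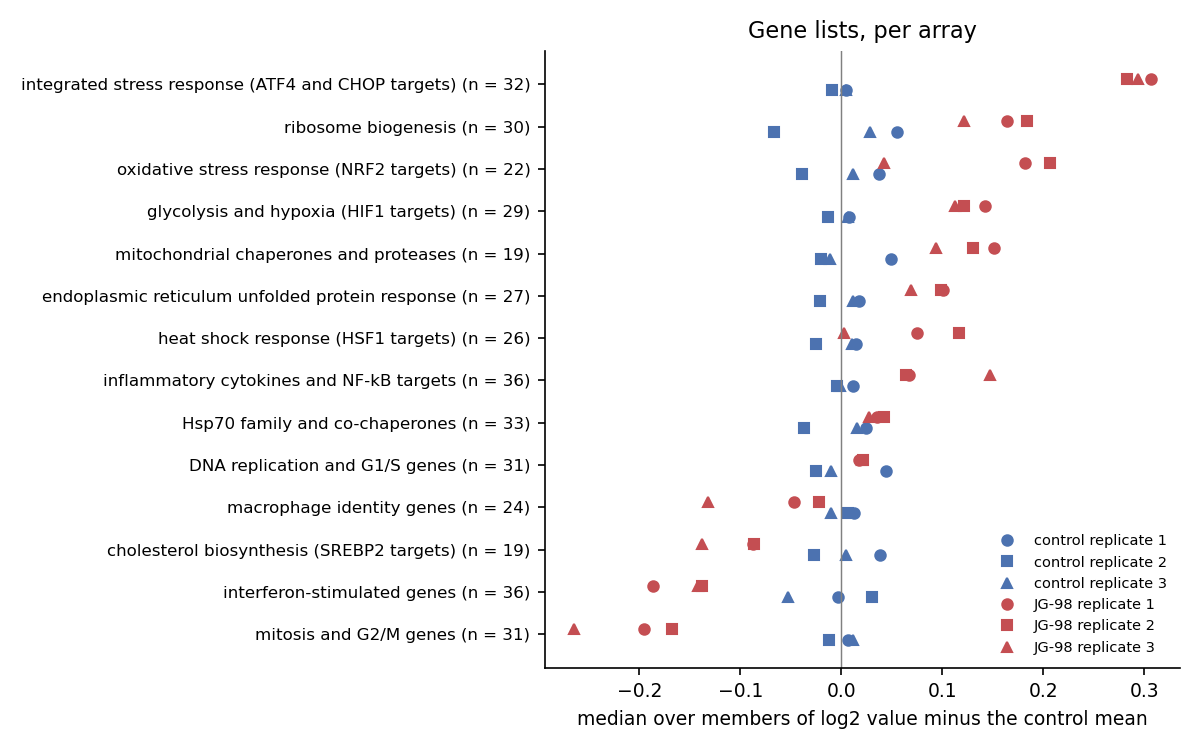
Median over the members of each gene list of the log2 value minus the control mean (horizontal axis), with a point for each control (blue) and JG-98 (red) array. It covers the 11 lists that passed camera at its preset correlation and the heat shock, Hsp70 and G1/S lists, and the median differences run from -0.21 for mitosis to 0.25 for the integrated stress response.

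The other lists did not pass camera. Members of some passed in both directions when adjusted over the list alone. Of 30 tumour-supporting and angiogenic factors, 4 rose, among them Vegfa and the urokinase receptor gene Plaur at 0.46 ± 0.089, and 3 fell, among them Mmp8 at -0.77 ± 0.082 and Thbs1 (camera adjusted p = 0.61). The immediate early genes had 4 that rose, with Klf4 and Myc, and 3 that fell, with Ier3 (adjusted p = 0.15). The p53 targets had 3 that rose, with Gadd45a at 0.57 ± 0.069, and 3 that fell, with Sesn1 (adjusted p = 0.67). Alternative activation markers had 2 that rose and 1, Irf4, that fell (adjusted p = 0.77), and phagocytosis receptors had Marco higher, at 0.65 ± 0.099, and Abca1 lower (adjusted p = 0.56). Of the chemotaxis receptors, P2ry12 at -0.85 ± 0.13, Cxcr4 at -0.36 ± 0.061 and Csf2rb fell (adjusted p = 0.075). Bcl2 rose among apoptosis regulators (adjusted p = 0.99), and Ulk1 fell among autophagy and lysosome genes (adjusted p = 0.61). Most of these counts moved when 1 array was left out. Without control replicate 2 they were 1 up and 1 down for tumour-supporting factors, 1 and 0 for immediate early genes, 1 and 0 for alternative activation, and 0 down for the chemotaxis receptors. Without control replicate 1 they were 2 and 1 for tumour-supporting factors, 3 and 0 for immediate early genes, and 0 and 0 for alternative activation. For tumour-supporting factors they were also 2 and 2 without control replicate 3, and 2 and 1 without JG-98 replicate 1 or JG-98 replicate 3. Without JG-98 replicate 2, 1 immediate early gene fell. Marco was lost without control replicate 2 or control replicate 3, and Abca1 among phagocytosis receptors without these or JG-98 replicate 2. The apoptosis count of 1 was 0 without any one array other than JG-98 replicate 3, and the Ulk1 call was lost without any one of the 6.

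No member passed in the lists of MHC class II presentation (camera adjusted p = 0.055), proteasome subunits (0.075), nuclear-encoded oxidative phosphorylation (0.15), cytosolic ribosomal proteins (0.83), YAP and TAZ targets (0.92) and replication-dependent histones (0.86). Without JG-98 replicate 3, camera called the lists of proteasome subunits (median 0.09, adjusted p = 5.1e-04) and oxidative phosphorylation (median 0.03, adjusted p = 0.017), as it did without control replicate 1. Of 15 settings, the MHC class II list passed in 6, the proteasome list in 5, the chemotaxis receptors in 4, and the oxidative phosphorylation and cholesterol efflux lists in 2 each. Among other cell types, none of the lists passed, with camera adjusted p-values of 0.88 for neutrophil, 0.23 for dendritic cell, 0.86 for B cell, 0.77 for T and NK cell, 0.98 for mast cell, 0.38 for erythroid, 0.77 for stromal, 0.28 for endothelial and 0.56 for osteoclast markers. On JG-98 replicate 3, the median deviation from the other 5 arrays was above 0 in each of these 9 lists, from 0.07 for erythroid to 0.22 for endothelial markers. Level-matched random lists also lay above 0 there, with middle values of 0.05 to 0.15. Of the 9 lists, 8 lay above their own middle value, at percentiles of 54.1 to 94.9, and the erythroid list lay below its own, at 34.7. All 120 markers together were at percentile 98.53. Adjusted over the list alone, the neutrophil markers Lcn2 and Mmp8 rose and fell, and the B cell markers Ms4a1 and Fcer2a rose and fell. The Lcn2 call was lost without JG-98 replicate 1 or JG-98 replicate 3. Both B cell calls, at mean levels of 1.7 to 2.5 where background is not excluded, were lost without control replicate 2, control replicate 3 or JG-98 replicate 1. The median, mean and camera direction differed in sign for the lists of apoptosis regulators, phagocytosis receptors, ribosomal proteins, B cell markers and mast cell markers.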

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

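The check of counts without JG-98 replicate 3 for list members was chosen after the results were seen, and the other settings were fixed earlier. The 10 genes kept their direction under all settings. Limma called 7 genes after median centring (5 higher), 90 without the dimmer probe sets by the stricter filter (49 higher, 41 lower, 8 by 2-fold), 254 with an intensity trend (127 higher, 127 lower, 9 by 2-fold) and 25 with array weights (17 higher, 8 lower, 8 by 2-fold). It called 0 with the replicate block (0 higher, 0 lower, 0 by 2-fold, smallest adjusted p = 0.22), where 1855 probe sets had an unadjusted p under 0.05. Leaving out 1 array gave 0 to 5 genes (0 to 4 higher, 0 to 1 lower, 0 to 5 by 2-fold), with fewer samples per fit. The cause was not tested for the stricter filter, the trend or the weights. Deviations from the group means gave no sign that replicate numbers pair the samples: same-numbered arrays correlated at 0.095, -0.126 and 0.104. Control replicate 1 correlated best with JG-98 replicate 2 (0.203). With 3 arrays per group, deviations from the group mean are tied to each other, so pairing is not excluded.

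Fry called 11 lists (7 higher, 4 lower), among them cholesterol efflux (fry adjusted p = 0.020), which camera did not call. Of the lists that camera called, only macrophage identity was lost in fry (fry adjusted p = 0.23). The highest fry adjusted p of the others was 0.045, close to the threshold. Camera called 17 lists with an intensity trend (7 lower), and 1 with an estimated correlation (1 higher, 0 lower). The estimated correlation was below the preset for the inflammatory list, which was still lost, so correlation between members does not account for every loss. It was 0.0025 for the integrated stress response list, also below the preset, and the unadjusted camera p still rose from 9.4e-27 to 2.9e-04. A reason other than correlation between members thus raised p in both lists, and it was not examined. Leaving out 1 array gave 12 to 14 lists, with 7 to 11 of them higher and 11 only without JG-98 replicate 3. Of the 11 called lists, 10 passed in 14 or 15 of 15 settings and macrophage identity in 8. Other than the estimated correlation and fry, these settings used camera at its preset correlation on nearly the same arrays. The tally is thus largely a repeat of 1 test. The robust prior has no bearing on camera, and averaging probe sets moves nothing.

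Signs turned only for uncalled results. After median centring Hspa8 was -0.012, and list medians were -0.0029 for p53 targets, -0.0063 for alternative activation, -0.0067 for tumour-supporting factors, -0.019 for ribosomal proteins, -0.0096 for YAP targets and -0.0059 for neutrophil markers. Quantile normalization gave 0.011 for apoptosis regulators and -0.0017 for alternative activation. The milder filter gave -0.033 for alternative activation and -0.021 for phagocytosis. The stricter one gave -0.063 and -0.084 for these, -0.0029 for YAP targets, -0.077 for neutrophil and -0.0998 for T and NK markers. Array weights gave 0.0062 for autophagy, 0.018 for apoptosis regulators, -0.079 for alternative activation, -0.045 for YAP targets, -0.034 for neutrophil markers, -0.077 for T and NK markers and 0.075 for histones.

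Leaving out 1 array gave ranges of -0.28 to 0.39 for Hspa1b, -0.050 to 0.054 for Hspa8, -0.018 to 0.57 for Hspa1a, -0.044 to 0.0048 for apoptosis regulators, -0.066 to 0.041 for alternative activation, -0.025 to 0.024 for phagocytosis, -0.048 to 0.034 for YAP targets and -0.062 to 0.10 for neutrophil markers. They were -0.018 to 0.16 for erythroid, -0.026 to 0.098 for stromal, -0.12 to 0.13 for B cell, -0.034 to 0.033 for mast cell and -0.096 to 0.034 for T and NK markers. They were -0.073 to 0.12 for histones, -0.0011 to 0.040 for G1/S genes, -0.042 to 0.050 for ribosomal proteins, -0.00027 to 0.025 for tumour-supporting factors and -0.032 to 0.019 for autophagy. Dim probe sets such as Hspa1a lie near background, which limits what their values show.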

Other observations

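The rules for the tests of explanations in this part were written down only after the results were seen, and the splits of the samples, a standard count, were also run then. Leaving out each array was fixed earlier. Genes and families outside the rule for naming were chosen after their values were seen. Families were adjusted over the family alone, and single genes over the integrated stress response list alone, with limma.

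Further single genes of the integrated stress response list, chosen after their values were seen, rose when adjusted over the list alone, and none of the 5 passed over all genes (limma adjusted p from 0.089 for Slc7a5 to 0.305 for Chac1). Slc7a5, a carrier of large neutral amino acids, was 0.88 ± 0.093 higher on the log2 scale (SE, n = 3 per group). Atf4 was 0.44 ± 0.088 higher, Ddit3, which encodes CHOP, 0.84 ± 0.16, Atf5 0.68 ± 0.086 and Chac1, a glutathione-degrading enzyme, 0.77 ± 0.16.

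The Ms4a family of membrane proteins had 20 measured genes, of which Ms4a4a fell over all genes. Adjusted over the family alone, Ms4a4c at -0.93 ± 0.12 and Ms4a6b at -0.80 ± 0.13 also fell and Ms4a1 at 0.28 ± 0.067 rose (limma adjusted p over all genes 0.126, 0.220 and 0.362). Background is not excluded for Ms4a4c, at mean levels of 2.5 to 3.4, or for Ms4a1, at 1.7 to 2.0. Guanylate-binding proteins, GTPases induced by interferon, had 10 measured genes, of which 5 fell adjusted over the family alone and 0 over all genes (limma adjusted p from 0.133 for Gbp7 to 0.502 for Gbp5). They were Gbp7 at -1.07 ± 0.14, Gbp9, Gbp3, Gbp2 and Gbp5, which was at -0.49 ± 0.16 and at -0.30 without control replicate 1. Of these, Gbp2 and Gbp5 did not pass adjusted over the interferon-stimulated list alone (adjusted p = 0.067 and 0.10). Background is not excluded for Gbp3, at mean levels of 2.7 to 3.5, or for Gbp5, at 3.0 to 3.5. Close relatives in both families can share probes, so single members are uncertain.

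For the counts, the 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 10 genes, 5 of them by 2-fold or more, and the highest other split called 0 of either, so 1 of 10 splits gave as many in both counts. For gene lists, 2 of 10 splits gave at least as many as the real 11, and the highest other gave 13. That split set control replicate 1, JG-98 replicate 1 and JG-98 replicate 2 against the others, called 0 genes and had 2636 probe sets at an unadjusted p under 0.05. It parts the arrays along the first principal component, so camera calls at the preset correlation also follow a structure of the samples other than the treatment. Of the 11 called lists, 10 had their smallest camera p in the real split and 9 their largest absolute median, as another split gave 0.074 for the inflammatory list and 0.120 for the mitochondrial chaperones.

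JG-98 replicate 3 lay apart from the other 5 arrays, with an SD of its deviations of 0.258 on the log2 scale. A compressed intensity scale was first tested by the correlation of its deviation with mean level across probe sets, -0.27, which met neither bound set for it, and a second test was then put in its place. After quantile normalization the SD was still 0.242, against at most 0.189 for another array, which argues against compression as the whole cause. RNA from another cell type may contribute: its 120 markers lay at percentile 98.53 of level-matched random lists, which met the first rule for that explanation. The rule was then tightened to ask also for a single cell type, and the highest single list, endothelial, was at 94.93, so this stays open. The marker lists had median levels of 2.36 (mast cell) to 4.43 (osteoclast), low values for which background is not excluded.

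The integrated stress response list was higher with JG-98. Its median lay at percentile 100 of 10000 level-matched random lists, and it was 0.258 without JG-98 replicate 3, which argues against a shift shared by genes of that level and against that array alone. If this is an ATF4 program, cytosolic but not mitochondrial tRNA synthetases outside the list could be raised. Of 13 cytosolic genes 12 were higher and 3 rose adjusted over the family alone, with a median at percentile 99.91, while 0 of 16 mitochondrial genes did so, at percentile 91.12. The medians differed by 0.072 (permutation p over genes = 0.0705, two-sided, and genes are not independent replicates), so this is not decided, and the ATF4 explanation is a hypothesis set up and tested on the same data.

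The mitosis list was lower with JG-98. Its median lay at percentile 0 of level-matched random lists and was -0.176 without JG-98 replicate 3, which argues against the same 2 technical explanations. Fewer cells in G2 and mitosis is a candidate explanation: 38 mitotic genes outside the list were all lower, with a median of -0.20 at percentile 0. Mitotic genes vary together, so this is close to a repeat of the first result, and lower transcription in the same number of cells would look alike. The estimated-correlation test did not call the list, while fry did (fry adjusted p = 0.020), and cells were not counted here.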
